A study of Mus musculus with 6 samples.

How the data were processed

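RNA of the liver was sequenced from 6 male C57BL/6 mouse samples aged 71 weeks, 3 on normal chow and 3 on chow with polypropylene microplastic (PP-MP). Per the labels, total RNA was purified with a Direct-zol kit, poly(A) RNA was selected, and directional libraries were made with the NEBNext Ultra II kit. Dose, particle size and length of exposure are not given in the sources used here. The deposited table holds raw read counts per gene, 56674 rows by gene symbol, and the 6 deposited per-sample files of counts are identical to their columns. Per the submitters' processing notes, base calls were converted with bcl2fastq and reads were mapped to GRCm39, without versions. The aligner, the counting tool, the strand setting and the annotation are not given in the sources used here. Counts on nuclear copies of mitochondrial genes, 0.990 to 0.997 on a copy of mt-Co2 per count on mt-Co2, show that the same reads were probably counted at more than 1 gene.

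The groups, the comparison, 42 gene lists, the tests and the alternatives were fixed before the data were examined. Groups follow the sample titles and characteristics, since the treatment protocol names PS-MP for every sample. The labels do not say that replicate numbers pair samples across diets, so the comparison is unpaired. Correlations of same-numbered samples were −0.0662, −0.0872 and 0.0470, which gives no sign of pairing but cannot exclude it with 3 libraries per group. No pair of libraries within a group was a duplicate (chi-square per degree of freedom 154 to 928, over genes with at least 20 counts in both). A symbol on more than 1 row (67 symbols, 939 rows, 0.0304% of all counts) was kept row by row. Symbols were matched to GENCODE M21 (GRCm38) for gene class, exonic length and overlapping gene models, which covered 91.4% of the 30797 rows with a count, and no coordinates are given because that build differs from GRCm39. Of 1030 list entries 1019 matched by symbol, 9 through a RefSeq synonym and 2 not at all, and 920 unique members were tested.

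Total counts were 75897165, 68357478 and 112566641 in control 1, 2 and 3 and 91936078, 81073738 and 100252360 in PP-MP 1, 2 and 3. Counts were filtered with filterByExpr by group, scaled with TMM factors (0.957, 0.882 and 0.929 in control 1, 2 and 3; 1.10, 1.12 and 1.03 in PP-MP 1, 2 and 3) and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 18284 genes and a threshold of 0.05. Standard errors and 95% intervals of log2 fold changes come from the same fit, and an interval within 1 on the log2 scale is called within 2-fold. Log2 CPM used a prior count of 2. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over 42 lists, and again with a correlation estimated per list and with fry. List means per library were compared with an exact permutation test, whose smallest two-sided p with 3 against 3 is 0.1. For each list, gene p-values were also adjusted over the list alone. Genes named singly are, in each direction, those past the threshold, filled up to 12 with the genes of smallest unadjusted p, all with a mean CPM of at least 1 and no overlap between the groups. Predicted genes without a name and pseudogenes were not named. For the lists described, members of smallest p are named, at most 4 per list. Heat shock, unfolded protein, p53, circadian, pericentral, periportal, ribosomal protein and liver tumour lists missed the camera threshold, and none of their members is named. Cyp2b10, Cyp2c29, Elovl3 and Serpina1e fall outside this rule and were chosen after their values were seen. A group with 0 counts was given a floor of 3 counts per library. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 served for tables and figures.

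Alternatives were DESeq2 size factors in edgeR, library totals in place of TMM factors, no filter on low counts, a filter at a mean CPM of 1, the DESeq2 1.42.0 test, limma-voom, a block for replicate number, a threshold of 0.1, the data without mitochondrial and haemoglobin genes, and each library left out in turn. Chosen after seeing the data were control 2 and PP-MP 1 left out together, the data without ribosomal RNA genes and unprocessed pseudogenes, and removal of a trend with gene length (lowess span 0.3). The procedure was tested on simulated data with 17826 genes in step and 200 changed genes, drawn from genes with a mean CPM of at least 1. It made 40 calls, 0 of them false, and recovered 0% of 67 genes changed 1.5-fold, 8.96% of 67 changed 2-fold and 51.5% of 66 changed 4-fold. Its 95% intervals covered the simulated value for 95.4% of genes, and the 1 shifted list was called (median log2 fold change −0.68, adjusted p = 1.7e-07). Genes were simulated independently of one another, so the simulation does not test list calls where genes are correlated.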

Results

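Liver RNA was sequenced from male C57BL/6 mice, a common inbred laboratory strain, that were kept to 71 weeks on normal chow (control, 3 samples) or on chow with polypropylene microplastic (PP-MP, 3 samples). Polypropylene is a widely used packaging plastic. The question named for the series is whether long exposure alters hepatic gene expression and the metabolism of the animals. The treatment protocol in the labels names PS-MP for every sample, while the titles and characteristics name PP-MP or normal chow, and the groups follow the latter. The labels do not say that replicates were separate animals, so the p-values measure the spread between these samples. Total counts ranged from 68357478 (control 2) to 112566641 (control 3) per library. Libraries of the same group differed by far more than counting error (chi-square per degree of freedom 154 to 928 between pairs), so the intervals of fold changes rest on the spread between libraries.

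The libraries of the 2 diets differed in RNA classes. The 18S ribosomal RNA gene Rn18s-rs5 took 5.08% ± 5.36 of the counts in control (SD, n = 3) and 0.704% ± 0.0479 in PP-MP. Control 2 held the highest share, 11.2%, and control 3 the lowest control share, 1.15%, which was still above the highest PP-MP share of 0.750%. The 95% Wilson intervals of these shares reached at most 0.00747 percentage points to either side, and they cover counting error only. Long non-coding RNA genes took 0.333% ± 0.0399 of the counts in control and 0.460% ± 0.0151 in PP-MP, again without overlap. A count was seen for 23551 ± 406 genes in control and 25389 ± 470 in PP-MP. The first principal component of log2 CPM held 38.1% of the variance, with control at −75.9, −9.32 and −67.3 and PP-MP at 75.4, 42.5 and 34.6. Control 2 stood apart on the second component (20.5% of the variance), at −90.3. No batch is named in the labels, so a batch that coincides with the diet cannot be told apart from it.

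**Figure D1:**
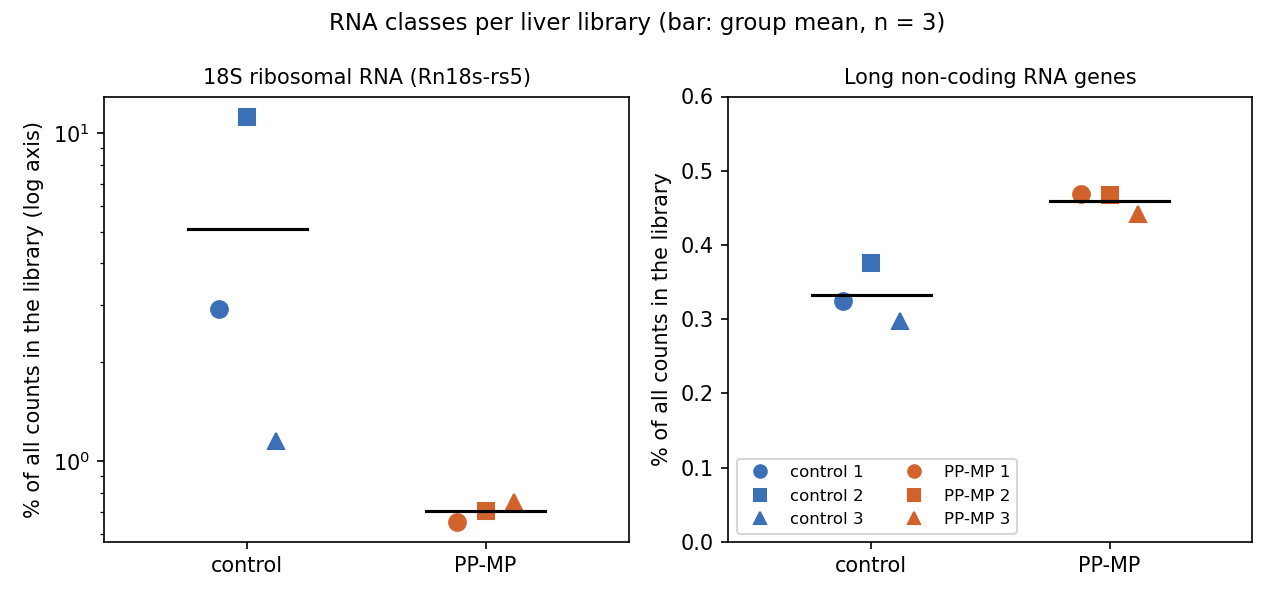
Share of all counts per library (%) taken by the 18S ribosomal RNA gene Rn18s-rs5 (left, log axis) and by long non-coding RNA genes (right), for 3 control (blue) and 3 PP-MP (orange) libraries, with bars at the group means. The groups do not overlap in either panel, and control 2 reaches 11.2% ribosomal RNA.

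Among single genes, Arhgap23, a GTPase-activating protein, rose and Cyp4a12b, a cytochrome P450 that hydroxylates fatty acids and is known for its higher expression in males, fell in the livers of PP-MP mice. Arhgap23 went from 0.273 ± 0.0482 CPM in control to 9.86 ± 2.07 CPM in PP-MP (mean ± SD, n = 3 per group), a log2 fold change of 5.16 (SE 0.28, edgeR quasi-likelihood adjusted p = 0.0097). Cyp4a12b went from 171 ± 17.3 to 37.2 ± 4.56 CPM, a log2 fold change of −2.20 (SE 0.16, edgeR adjusted p = 0.032). These were the 2 genes past the threshold among 18284 tested, 1 higher and 1 lower. The near-identical neighbour Cyp4a12a had a log2 fold change of −2.14 (SE 0.23) and missed it (edgeR adjusted p = 0.13), and reads of the pair may have been counted for either gene. The gene model 4933428G20Rik, singled out after its values were seen because its exons overlap Arhgap23 in the annotation used for gene classes, was at 0.228 ± 0.142 CPM in control and 0.182 ± 0.0352 CPM in PP-MP.

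Other genes chosen by the naming rule were separated between the groups in every library but missed the edgeR threshold, with adjusted p from 0.13 to 0.18. On the higher side, Marco, a scavenger receptor of macrophages, was at 2.83 ± 1.10 CPM in control and 76.2 ± 57.5 CPM in PP-MP (log2 fold change 4.76, SE 0.72, n = 3 per group). Smg1, a kinase of nonsense-mediated mRNA decay, had a log2 fold change of 5.59 (SE 0.67), with PP-MP libraries at 25.6, 37.4 and 7.22 CPM against 0.486 ± 0.0986 CPM in control. Zmym2 (log2 fold change 2.69), Tbc1d24 (2.13), Adamts6 (1.98), N4bp2os (1.55), Manea (1.52), Rbm4b (1.46), Metap1d (1.23), Nrbp2 (1.20) and Nlrc5, a transactivator of MHC class I genes (1.02), completed that side. On the lower side, Scd3, a stearoyl-CoA desaturase, had 23.6 ± 12.9 CPM in control and 0 counts in all 3 PP-MP libraries, at least 772-fold lower when 3 counts per library were taken as the floor, which covers counting error only. Scd3 is similar in sequence to Scd1. Reads of Scd1, which was expressed in PP-MP livers (values below), were not counted for Scd3 there, since Scd3 had 0 counts. Reads of Scd3 may still have been counted for Scd1, so this value is uncertain. Kcnn1, a calcium-activated potassium channel, had a log2 fold change of −4.64 (SE 0.46), Cyp2c55 −2.64 (SE 0.29) and Gstm3, a glutathione S-transferase, −2.30 (SE 0.30). The rest were Hnf4aos (−2.26), Gal3st1 (−1.98), Dpy19l3 (−1.47), U2af1l4 (−1.45), Cyp3a25 (−1.32) and Setd3 (−0.995). N4bp2os and Hnf4aos are named as opposite-strand genes, and Rbm4b, Tbc1d24, Nrbp2, Nlrc5, Kcnn1, Cyp2c55 and U2af1l4 share exonic positions with another gene model, so their counts are uncertain.

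Across all genes, edgeR gave 2535 genes an unadjusted p under 0.05, and 2228 genes were higher and 1790 lower in every PP-MP library than in every control library, 22.0% of those tested against 10% by chance. DESeq2 called 777 genes (436 higher, 341 lower), limma-voom 1 (Cyp4a12b; adjusted p = 0.0501 for Arhgap23), and edgeR with library totals in place of TMM factors 1 higher (Arhgap23) and 0 lower (adjusted p = 0.084 for Cyp4a12b). Without control 2, edgeR called 92 genes (34 higher, 58 lower), 2 of them Arhgap23 and Cyp4a12b. The log2 fold changes moved little when 1 library was left out (5.02 to 5.32 for Arhgap23 and −2.28 to −2.11 for Cyp4a12b). Without control 1, control 3, PP-MP 1 or PP-MP 2 edgeR called 0 (adjusted p = 0.12, 0.078, 0.086 and 0.086 for Arhgap23 and 0.23, 0.16, 0.15 and 0.22 for Cyp4a12b). Without PP-MP 3 it called 2, both higher, of which Arhgap23 was 1 (adjusted p = 0.11 for Cyp4a12b). Leaving out control 2 and PP-MP 1 together, the 2 libraries that stood apart, also gave 2 genes, neither of them Arhgap23 (adjusted p = 0.11) nor Cyp4a12b (adjusted p = 0.11). Over these and the other alternatives the adjusted p of Arhgap23 ranged from 7.4e-51 to 0.31 and that of Cyp4a12b from 1.8e-27 to 0.40. The 95% interval of the log2 fold change lay within 2-fold for 8457 genes, 46.3% of those tested (exact binomial 95% interval 45.5 to 47.0), and the interval reached a median of 0.73 to either side on the log2 scale.

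**Figure D2:**
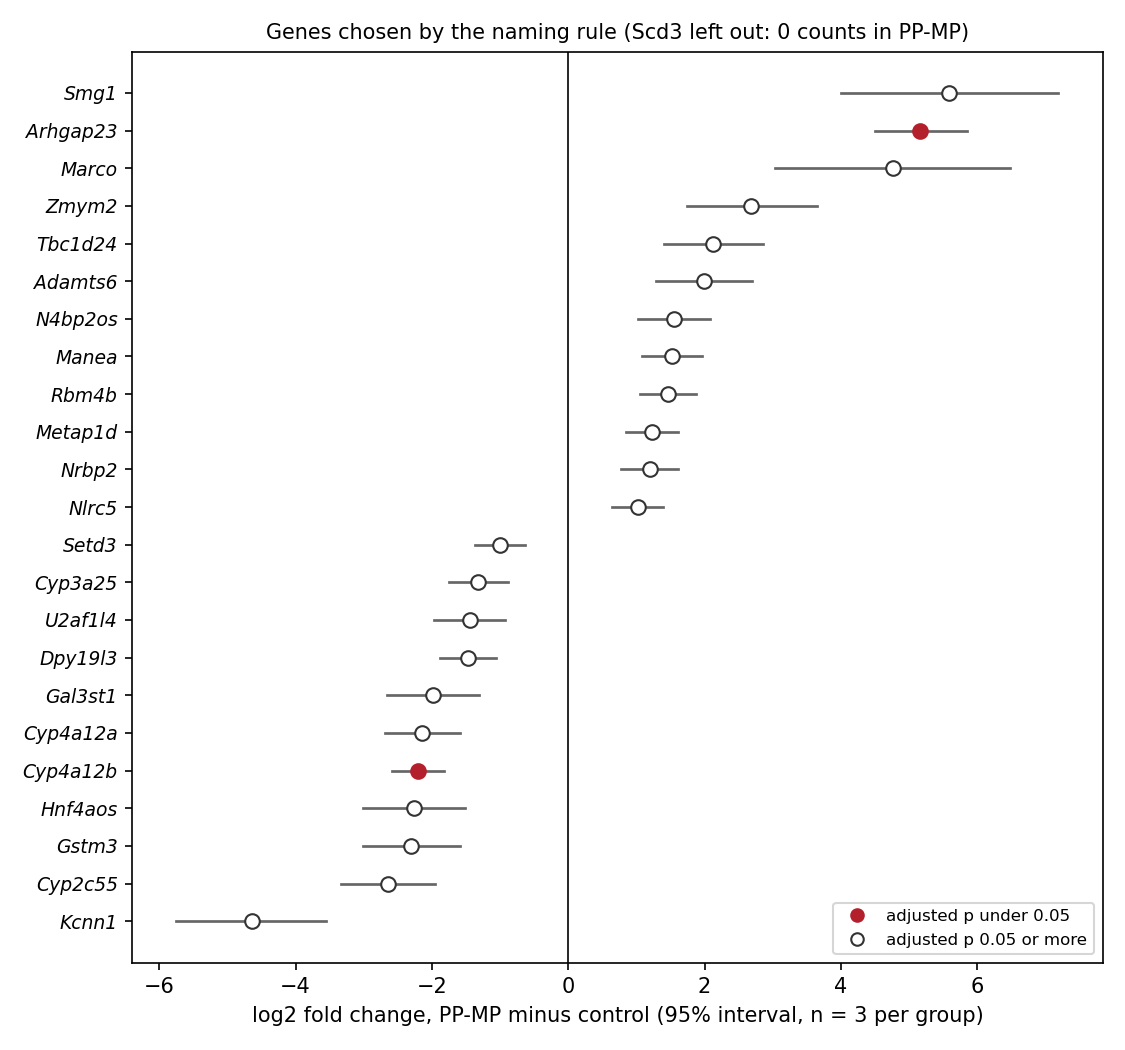
Log2 fold change (PP-MP minus control, x axis) with its 95% interval for 23 genes chosen by the naming rule, n = 3 libraries per group; filled points passed the edgeR adjusted p threshold. Arhgap23 (5.16) and Cyp4a12b (−2.20) are the filled points. No interval crosses 0, which the choice of genes without overlap and with the smallest p makes likely.

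Genes that metabolise foreign compounds were lower in PP-MP livers. The list of xenobiotic enzymes under control of the nuclear receptors CAR and PXR fell as a set, with a median log2 fold change of −0.69 over 35 genes (camera adjusted p = 2.9e-15; adjusted p = 0.82 with an estimated correlation). The estimated correlation was 0.32 in this list and ranged from 0.11 (male-biased) to 0.85 (acute phase) over the 13 lists called. The preset of 0.01 lies far below these. Of 10 splits of the libraries, 7, the real one among them, gave at least 13 lists with the preset. Camera p-values here and below therefore do not separate the diet from other splits, and "as a set" gives a direction only. Of its members, 30 had a lower and 5 a higher fitted value, and 17 were lower in every PP-MP library than in every control library. Cyp2b10, the best known CAR target, was at 7.0 ± 3.53 CPM in control and 0.825 ± 0.396 CPM in PP-MP (log2 fold change −3.09, SE 0.56). Cyp2c29 was at 1536 ± 174 and 554 ± 198 CPM. Gstm1 was at 2382 ± 513 and 899 ± 168 CPM, and Cyp3a25 at 162 ± 27.3 and 65.0 ± 8.78 CPM (SD, n = 3 per group). With edgeR, 13 members including these 4 fell when adjusted over the list alone and 0 passed over all genes tested, while 15 had an unadjusted p under 0.05 and DESeq2 called 10, all lower. Relative to the control mean the list stood at −1.64 in PP-MP 1, −0.40 in PP-MP 2 and −0.51 in PP-MP 3 (mean log2 CPM; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). PP-MP 1 was also the library with the highest acute phase and neutrophil values, and without it the list median was −0.46.

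Antioxidant genes controlled by NRF2 fell as a set, with a median log2 fold change of −0.42 over 25 genes (camera adjusted p = 3.4e-07; adjusted p = 0.82 with an estimated correlation). Gsta1, a glutathione S-transferase, was at 19.3 ± 4.71 CPM in control and 1.95 ± 1.21 CPM in PP-MP, and Gsta4 at 70.9 ± 5.09 and 25.9 ± 10.8 CPM. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, was at 368 ± 83.5 and 188 ± 46.3 CPM (SD, n = 3 per group). These 3 were among 8 members that fell when adjusted over the list alone, and 0 passed over all genes tested with edgeR, while 11 members had an unadjusted p under 0.05 (1 higher, 10 lower) and DESeq2 called 7, all lower. Relative to the control mean the list stood at −0.79, −0.50 and −0.51 in PP-MP 1, 2 and 3 (exact permutation p = 0.1, two-sided), and its median was −0.28 without PP-MP 1 and −0.19 with library totals. Some glutathione S-transferases of a class are closely similar in sequence, and reads may have been counted for more than one of those.

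Genes of fatty acid synthesis also fell as a set. The lipogenesis list of SREBP1c and ChREBP targets had a median log2 fold change of −0.37 over 23 genes (camera adjusted p = 3.9e-06; adjusted p = 0.82 with an estimated correlation). Relative to the control mean the list stood at −0.62, −0.21 and −0.53 in PP-MP 1, 2 and 3, against −0.32 in control 2 (exact permutation p = 0.2, two-sided). Scd1, the main hepatic stearoyl-CoA desaturase, was at 5698 ± 2030 CPM in control and 1387 ± 309 CPM in PP-MP (log2 fold change −2.04, SE 0.33, n = 3 per group). Scd2 was at 13.6 ± 5.05 and 5.16 ± 1.13 CPM, and Me1, the cytosolic malic enzyme, at 225 ± 98.8 and 79.8 ± 28.0 CPM. Mlxipl, which encodes the transcription factor ChREBP itself, went the other way, from 56.4 ± 5.14 to 87.6 ± 9.22 CPM. Adjusted over the list alone, 6 members fell, among them Scd1, Scd2 and Me1, and Mlxipl rose. With edgeR 0 passed over all genes tested, 10 had an unadjusted p under 0.05 (1 higher, 9 lower), and DESeq2 called 7 (1 higher, 6 lower). The list of lipid droplet and fatty acid uptake genes fell with a median of −0.32 over 24 genes (camera adjusted p = 0.0098; adjusted p = 0.82 with an estimated correlation), with 0 members past the threshold over the list alone or over all genes, 3 at an unadjusted p under 0.05 and 0 by DESeq2. The mean of the lipid droplet list stood at −1.12, 0.11 and −0.54 in PP-MP 1, 2 and 3 relative to control (exact permutation p = 0.3, two-sided). Its leading members Pparg and Fitm1 had log2 fold changes of −0.67 and −1.31. That call was lost without PP-MP 1 (median −0.20, adjusted p = 0.26) and without control 3 (−0.13, adjusted p = 0.073; 3.2e-06 to 0.26 over the 6 left-out libraries), and the median was −0.20, −0.50 and −0.57 without control 1, control 2 and PP-MP 2. The lipogenesis median was −0.58 without PP-MP 2, and with library totals the lipogenesis and lipid droplet medians were −0.15 and −0.09.

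Mitochondrial respiration genes fell as a set in both genomes. The 50 nuclear genes of oxidative phosphorylation had a median log2 fold change of −0.33 (camera adjusted p = 6.4e-08; adjusted p = 0.82 with an estimated correlation), with 48 lower and 2 higher fitted values. Its median was −0.19 without PP-MP 1 and −0.11 with library totals. Relative to the control mean the list stood at −0.63, −0.27 and −0.06 in PP-MP 1, 2 and 3, against −0.16 in control 2 (exact permutation p = 0.2, two-sided). The leading members Sdha and Ndufa10, subunits of respiratory complexes, had log2 fold changes of −0.64 (SE 0.23) and −0.61 (SE 0.22), and 0 members passed over the list alone or over all genes with edgeR, while 5 had an unadjusted p under 0.05 and DESeq2 called 0. The 13 transcripts encoded by the mitochondrial genome had a median of −0.41 (camera adjusted p = 8.5e-04; adjusted p = 0.82 with an estimated correlation), 12 of them lower, and of −0.18 with library totals. Relative to the control mean these 13 stood at −0.97, −0.86 and −0.40 in PP-MP 1, 2 and 3 (exact permutation p = 0.1, two-sided). Another measure, the share of all counts without TMM factors, covered every gene of the mitochondrial genome and not these 13 alone. That share was 16.5% in PP-MP 1, above the 14.9% to 16.4% of the control libraries, and 11.6% and 13.5% in PP-MP 2 and 3. The cytochrome oxidase transcript mt-Co1 was at 51746 ± 2620 CPM in control and 32175 ± 4619 CPM in PP-MP, and mt-Nd1 at 12961 ± 1997 and 9243 ± 1076 CPM (SD, n = 3 per group). With edgeR 0 of the 13 passed over the list alone or over all genes, 1 had an unadjusted p under 0.05, and DESeq2 called 1, mt-Co1. A nuclear copy of mt-Co2 carried 0.990 to 0.997 counts per count on mt-Co2, and a copy of mt-Co1 0.177 to 0.223, so reads of these transcripts were probably counted more than once.

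Camera called fatty acid oxidation genes and other PPAR-alpha targets as lower, but among PP-MP libraries PP-MP 1 alone had a list mean below the control mean. By contrast, Cyp4a12a and Cyp4a12b were lower in every PP-MP library than in every control library. The PPAR-alpha list had a median log2 fold change of −0.15 over 36 genes (camera adjusted p = 5.7e-04; adjusted p = 0.82 with an estimated correlation), and its mean stood at −1.16 in PP-MP 1, 0.19 in PP-MP 2 and 0.15 in PP-MP 3 relative to control. The list means gave an exact permutation p of 0.8, two-sided. The 2 members that fell when adjusted over the list alone were Cyp4a12a and Cyp4a12b, which belong also to the male-biased list, and 1 of them, Cyp4a12b, passed over all genes. The next members by p missed the threshold, Hsdl2, a peroxisomal protein, with a log2 fold change of −0.39 and Fgf21, a hormone secreted in fasting, with 1.55. With library totals in place of TMM factors, which shift all genes alike, the median turned to 0.07 while the list stayed called as lower (adjusted p = 3.4e-04). The direction of the test turned, with loss of the call, without PP-MP 1 (median 0.14, adjusted p = 0.94; 1.4e-06 to 0.94 over the 6 left-out libraries). Without control 2 and PP-MP 1 together the call was lost and the median was 0.03 (adjusted p = 0.37), while the test kept its direction. The median was −0.07, −0.24 and −0.41 without control 3, PP-MP 2 and PP-MP 3. Liver genes known for higher expression in males had a median of −0.22 over 23 genes and were called as lower as a set (camera adjusted p = 2.6e-04; adjusted p = 0.82 with an estimated correlation), with 15 lower and 8 higher. Their list means gave an exact permutation p of 0.6, two-sided. Adjusted over the list alone, 5 fell and 1 rose, and 1 (Cyp4a12b) passed over all genes. Besides the Cyp4a12 pair, Elovl3 was at 408 ± 178 CPM in control and 142 ± 54.8 CPM in PP-MP, Ugt2b38 at 87.4 ± 16.3 and 51.6 ± 6.63 CPM, and Serpina1e, which rose, at 976 ± 448 and 4248 ± 2778 CPM (SD, n = 3 per group). That list lost its call without control 2 (median 0.19, adjusted p = 0.082; 1.9e-05 to 0.082 over the 6 left-out libraries), and without control 2 and PP-MP 1 together (0.02, adjusted p = 0.37). Its median was 0.02 with library totals, still called as lower relative to other genes (adjusted p = 3.7e-04), and −0.33, −0.13, −0.07 and −0.39 without control 3, PP-MP 1, PP-MP 2 and PP-MP 3.

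Macrophage genes were higher in PP-MP livers, most of all in PP-MP 1. The list of Kupffer cell and macrophage markers rose with a median log2 fold change of 0.90 over 28 genes, 25 of them higher (camera adjusted p = 4.2e-06; adjusted p = 0.82 with an estimated correlation). Its mean stood at 1.63 in PP-MP 1, 0.90 in PP-MP 2 and 0.03 in PP-MP 3 relative to control (exact permutation p = 0.2, two-sided). Marco rose when adjusted over the list alone and was higher in every PP-MP library. Timd4, a receptor of resident Kupffer cells, was at 1.94 ± 0.795 CPM in control and 10.2 ± 7.21 CPM in PP-MP, and Adgre1, which encodes F4/80, at 6.43 ± 1.37 and 25.7 ± 19.4 CPM (SD, n = 3 per group). With edgeR 0 members passed over all genes tested, 7 had an unadjusted p under 0.05, and DESeq2 called 4, all higher. Without PP-MP 1 the median was 0.41 (adjusted p = 0.012; 1.4e-19 to 0.012 over the 6 left-out libraries), and without control 2 and PP-MP 1 together the call was lost (median 0.32, adjusted p = 0.16).

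Acute phase genes, neutrophil markers and cytokine genes were called as higher as sets, with the highest values in PP-MP 1. The list means gave exact permutation p-values of 0.4 for acute phase, 0.3 for neutrophil and 0.2 for cytokine genes, two-sided. The 25 acute phase and complement genes had a median log2 fold change of 0.84 (camera adjusted p = 0.0023; adjusted p = 0.82 with an estimated correlation). Saa1, a serum amyloid of the acute phase, was at 1700 CPM in PP-MP 1, 20.6 CPM in PP-MP 2 and 5.25 CPM in PP-MP 3, against 7.52 ± 1.13 CPM in control (SD, n = 3). Itih3 was at 384 ± 30.3 CPM in control and 917 ± 487 CPM in PP-MP. The 8 neutrophil markers had a median of 1.97, all 8 higher (camera adjusted p = 0.017; adjusted p = 0.82 with an estimated correlation), and S100a8 and S100a9 rose when adjusted over the list alone (log2 fold changes 3.30 and 3.53). The 26 cytokine, chemokine and NF-kB target genes had a median of 0.78 (camera adjusted p = 0.020; adjusted p = 0.82 with an estimated correlation). Among them Cxcl1, a neutrophil attractant, was at 1.55 ± 0.222 and 17.7 ± 24.2 CPM, whereas Cxcl9, an interferon-induced T cell attractant, fell when adjusted over the list alone, from 10.2 ± 1.92 to 4.96 ± 0.261 CPM. Of the acute phase genes 0 passed when adjusted over the list alone. Over all genes tested 0 members of these 3 lists passed with edgeR, 8, 4 and 9 had an unadjusted p under 0.05, and DESeq2 called 1, 1 and 2. Without PP-MP 1 all 3 calls were lost (medians 0.07, 0.68 and 0.50; adjusted p = 0.64 for acute phase, 0.12 for neutrophil and 0.39 for cytokine genes, the highest over the 6 left-out libraries, where the lowest were 9.6e-09, 2.5e-08 and 1.3e-05), as they were without control 2, where the medians were 0.72, 2.42 and 1.005 (adjusted p = 0.23, 0.063 and 0.063). The neutrophil median was 3.19 without PP-MP 3. The cytokine call was also lost without control 1 (median 0.58, adjusted p = 0.098). The neutrophil and cytokine calls were lost with library totals (medians 2.23 and 1.03, adjusted p = 0.093 and 0.051) and with limma-voom (medians 1.49 and 0.81, adjusted p = 0.15 and 0.063), though the medians kept their direction.

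**Figure D3:**
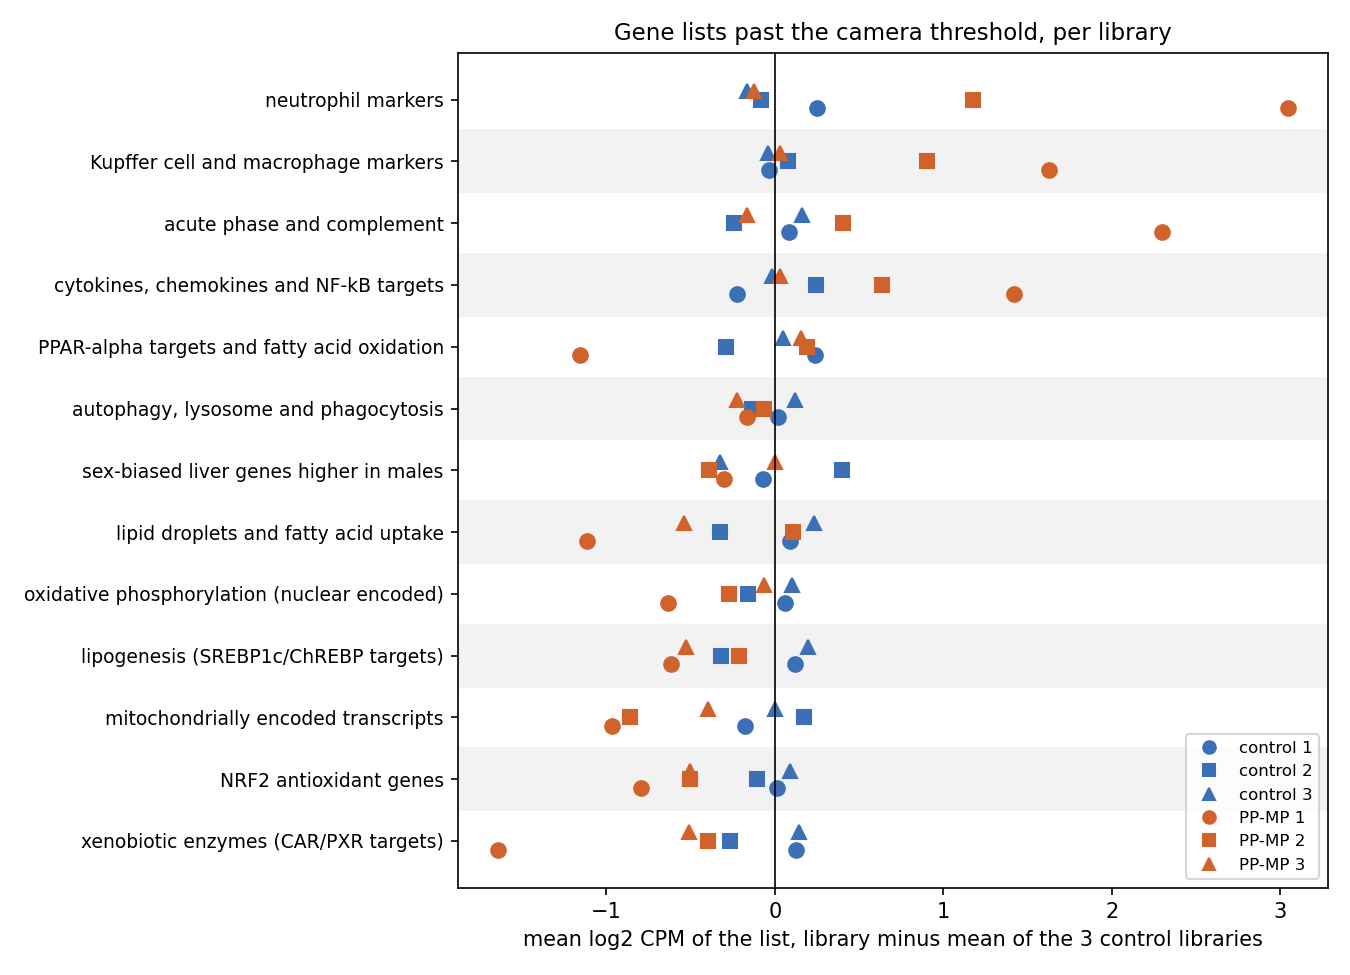
Mean log2 CPM of each of the 13 lists past the camera threshold, per library, minus the mean of the 3 control libraries (x axis); blue symbols are control and orange symbols PP-MP libraries. PP-MP 1 lies farthest from control in most lists, as for xenobiotic enzymes (−1.64) and neutrophil markers (3.05), and PP-MP 3 lies near control for macrophage markers (0.03).

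**Figure D4:**
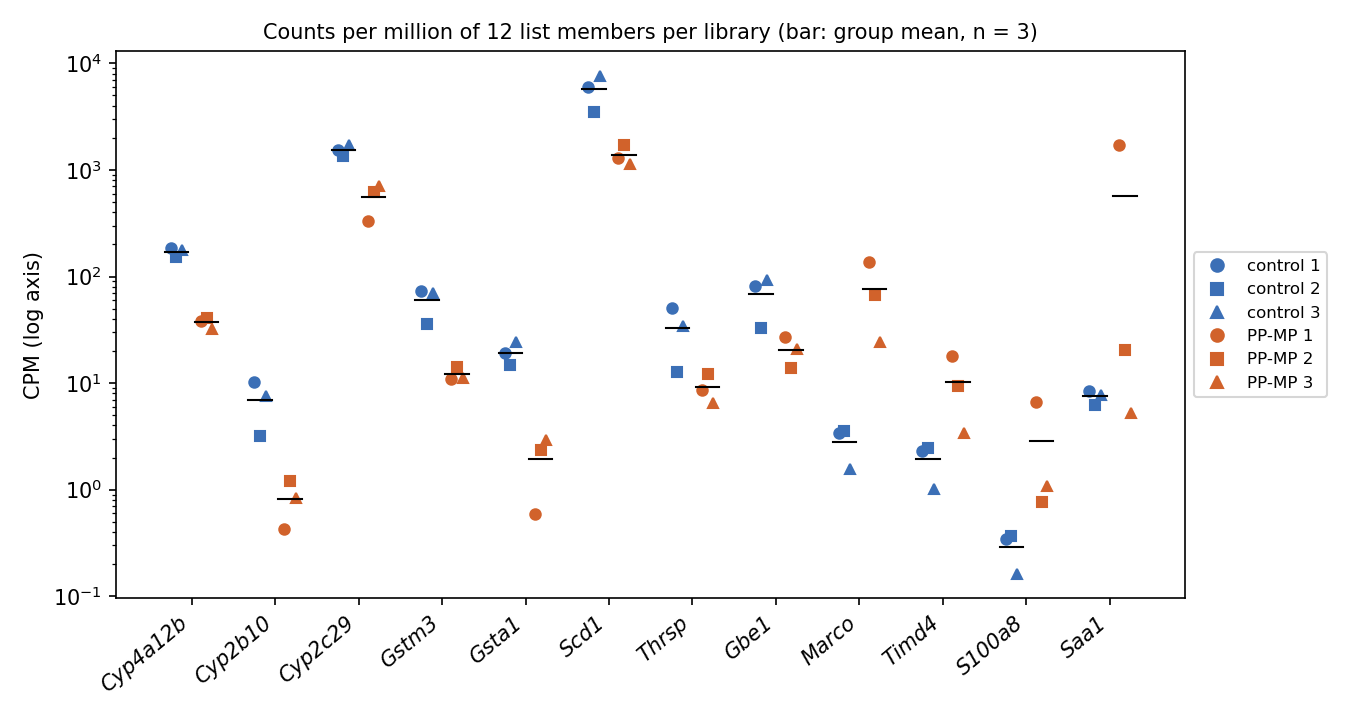
CPM (log axis) of 12 list members in each control (blue) and PP-MP (orange) library, with bars at the group means (n = 3). Saa1 reaches 1700 CPM in PP-MP 1 alone, while Cyp4a12b, Cyp2b10, Scd1 and Marco separate the groups in every library.

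Other metabolic lists missed the camera threshold. Within gluconeogenesis and glycogen (19 genes, median log2 fold change −0.11, camera adjusted p = 0.33), the glycogen enzymes Gbe1, at 68.9 ± 32.1 CPM in control and 20.5 ± 6.57 CPM in PP-MP, Pygl, at 238 ± 39.3 and 154 ± 10.8 CPM, and the glycogen-targeting subunit Ppp1r3c, at 95.1 ± 30.3 and 47.1 ± 6.83 CPM, fell when adjusted over the list alone (SD, n = 3 per group). In glycolysis and insulin signalling (26 genes, median −0.04, camera adjusted p = 0.33), Slc2a2, the main glucose transporter of hepatocytes, had a log2 fold change of −0.73 (SE 0.26) and Pgk1, a glycolytic kinase, −0.45 (SE 0.17). Cholesterol synthesis (25 genes, median −0.07, camera adjusted p = 0.18) had Nsdhl at −1.12 and Tm7sf2 at −0.75. That list passed as lower without control 2 (median −0.18, adjusted p = 9.5e-04) and without control 2 and PP-MP 1 together (−0.22, adjusted p = 0.0026), and turned without control 3 (0.10, adjusted p = 0.91). Bile acid synthesis and transport (24 genes, median −0.15, camera adjusted p = 0.11) had Abcg8 at −0.46 and Cyp2c70 at −0.67, and passed as lower without PP-MP 3 (median −0.23, adjusted p = 0.018; 0.018 to 0.26 over the 6 left-out libraries). Lipoproteins (20 genes, median −0.18, camera adjusted p = 0.16) had Apoa1 at 1.77 and Apoe at −0.66, and passed as lower without control 2 (median −0.24, adjusted p = 0.028; 0.028 to 0.45 over the 6 left-out libraries). Urea cycle and amino acid catabolism (26 genes, median −0.03, camera adjusted p = 0.85) had Gnmt at −0.57 and Mat1a at 0.54. AhR targets (10 genes, median −0.31, camera adjusted p = 0.24) had Ugt1a6a at −0.47 and Cyp1a1 at −0.68. The AhR median ranged from −0.68 to −0.05 over the 6 left-out libraries. Among drug and lipid transporters (23 genes, median −0.02, camera adjusted p = 0.23), Slc22a30 fell when adjusted over the list alone (log2 fold change −1.96, SE 0.32). The medians of the urea cycle and transporter lists differed in sign from the differences of their means (0.05 and 0.03). Over all genes tested edgeR called 0 members of these 8 lists, against 3, 6, 5, 0, 4, 2, 1 and 6 at an unadjusted p under 0.05 in the order given and 3, 2, 3, 0, 1, 0, 0 and 3 by DESeq2.

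Over the 336 genes of all 13 metabolic lists, 243 had a lower and 93 a higher fitted value in PP-MP livers, and the median log2 fold change was −0.24, against 0.03 for all genes tested. Per library, the median of the metabolic genes lay −0.51, −0.17 and −0.06 from the control mean in PP-MP 1, 2 and 3 and 0.10, −0.20 and 0.12 in control 1, 2 and 3, a difference within the spread between libraries (exact permutation p = 0.3, two-sided, where 3 against 3 can give 0.1 at the least). Cyp4a12b was the 1 metabolic gene past the threshold over all genes, and 9 passed when adjusted over the 336 genes alone. The 95% interval lay within 2-fold for 162 of them, 48.2%. Without TMM factors the median of all genes moved from 0.03 to 0.26 and that of the metabolic genes to −0.01. With that shift of all genes the signs of other medians turned too, in gluconeogenesis (0.12), glycolysis (0.19), cholesterol (0.16), bile acid (0.07), lipoprotein (0.05), urea cycle (0.20) and transporter genes (0.21). Leaving out single libraries moved the metabolic median between −0.36 and −0.12.

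Markers of other cell types and of neighbouring tissues, matrix genes and proliferation genes missed the camera threshold with all 6 libraries. Sinusoidal and vascular endothelial markers had a median log2 fold change of 0.15 over 24 genes (camera adjusted p = 0.51), with Mrc1 at 0.78 (SE 0.37), and stellate cell and fibroblast markers 0.08 over 19 genes (camera adjusted p = 0.99), with Hgf at 1.26 (SE 0.56). Cholangiocyte and gallbladder markers had a median of −0.18 over 14 genes (camera adjusted p = 0.32), with Krt23 at −2.13 (SE 0.84), and the median was 0.08 with library totals, 0.22 without control 2 (adjusted p = 0.95) and 0.24 without PP-MP 3, where the test turned (adjusted p = 0.97; 0.072 to 0.97 over the 6 left-out libraries). Erythrocyte markers had a median of 0.37 over 10 genes (camera adjusted p = 0.60; medians 0.11 to 0.56 over the 6 left-out libraries), with Fech at −0.39 (SE 0.13) and Hbb-bt at 0.92 (SE 0.38). Their mean was higher in every PP-MP library than in every control library (difference 0.35, exact permutation p = 0.1, two-sided), and without mitochondrial and haemoglobin genes the median was −0.10. Markers of pancreas, fat, muscle and gut, tissues that can be sampled with liver, had a median of 1.06 over 7 genes, 6 of them higher (camera adjusted p = 0.18), with the mesothelial genes Msln at 1.97 (SE 0.84) and Upk3b at 1.06 (SE 0.85). Their mean stood at 1.54 (PP-MP 1), 0.81 (PP-MP 2) and 0.58 (PP-MP 3) relative to control, against 0.60 in control 2 (exact permutation p = 0.2, two-sided). The median was 0.49 without PP-MP 1 and ranged from 0.42 to 1.61 over the 6 left-out libraries. Over all genes tested edgeR called 0 members of these 3 lists, against 2, 3 and 0 at an unadjusted p under 0.05 and 0 by DESeq2. T, NK and dendritic cell markers had a median of −0.31 over 23 genes (camera adjusted p = 0.081), with the T cell receptor gene Trac at −0.83 (SE 0.26). B and plasma cell markers had a median of −0.59 over 20 genes (camera adjusted p = 0.083), while the difference of their means was 0.07. Among them Ighm was at 338 and 57.6 CPM in PP-MP 1 and 2 and at 0.928 CPM in PP-MP 3, against 0.969 ± 0.138 CPM in control (SD, n = 3). Extracellular matrix and fibrosis genes had a median of 0.16 over 31 genes (camera adjusted p = 0.52), with Postn at 1.21 and Col1a2 at −0.75. They passed as higher without PP-MP 3 (median 0.42, adjusted p = 0.0042; 0.0042 to 0.93 over the 6 left-out libraries) and turned without PP-MP 1 (−0.11). Proliferation genes had a median of −0.37 over 30 genes (camera adjusted p = 0.089), with Rrm2 at −0.67 and Tyms at −0.43. Without PP-MP 1, the T cell, B cell and proliferation lists passed as lower (medians −0.35, −0.72 and −0.46; adjusted p = 0.021, 0.017 and 0.0016), as did T cell and proliferation lists without control 1 (adjusted p = 0.020 for both) and T and B cell lists without control 3 (adjusted p = 0.010 and 4.0e-04). Without control 2 the 3 medians were −0.06, −0.02 and −0.02 (adjusted p = 0.69, 0.81 and 0.50). With library totals all 3 lists passed as lower (medians −0.07, −0.33 and −0.13; adjusted p = 0.011, 0.0077 and 0.026).

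Autophagy and lysosome genes fell as a set, with a median log2 fold change of −0.16 over 29 genes, 19 lower and 10 higher (camera adjusted p = 0.027; adjusted p = 0.82 with an estimated correlation), a median that turned to 0.06, with loss of the call (adjusted p = 0.16), under library totals. The list means gave an exact permutation p of 0.2, two-sided. Atp6v1h, a subunit of the proton pump of lysosomes, was at 43.8 ± 4.45 CPM in control and 30.2 ± 3.35 CPM in PP-MP, Lipa, the lysosomal acid lipase, at 298 ± 43.8 and 199 ± 28.9 CPM, and Mertk, a receptor for the uptake of dying cells, at 11.2 ± 1.53 and 16.3 ± 2.86 CPM (SD, n = 3 per group). With edgeR 0 members passed over the list alone or over all genes, 4 had an unadjusted p under 0.05 (1 higher, 3 lower), and DESeq2 called 0. The call was lost without control 3 (median −0.08, adjusted p = 0.19), without PP-MP 3 (median −0.19, adjusted p = 0.12; 0.0063 to 0.19 over the 6 left-out libraries) and with a filter at a mean CPM of 1 (median −0.13, adjusted p = 0.12).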

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

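Leaving out control 2 and PP-MP 1 together, leaving out ribosomal RNA genes with unprocessed pseudogenes, and removing a gene length trend were chosen after seeing the data, and where no reason is given below, the cause was not tested. Of the alternatives, 2 genes passed with DESeq2 size factors in edgeR, no filter, a mean CPM of 1, a threshold of 0.1, and the data without mitochondrial and haemoglobin genes, without ribosomal RNA genes or without the length trend, in each case Arhgap23 and Cyp4a12b. With library totals 1 passed (lower 0), with limma-voom 1 (higher 0) and with the DESeq2 test 777 (higher 436, lower 341). With a block for replicate number 0 passed (higher 0, lower 0), though the labels do not say that the numbers pair samples. Without 1 library the count ranged from 0 to 92 (higher 0 to 34, lower 0 to 58). None of 384 values of the 24 genes chosen by the naming rule had the opposite sign under an alternative. This says little of robustness, since the rule asked for no overlap between the groups. Against 13 lists (4 higher, 9 lower), 14 passed with the block, 8 without control 2 and PP-MP 1 (higher 0), 0 with an estimated correlation (higher 0, lower 0) and 0 with fry (higher 0, lower 0). Library totals and limma-voom each left 2 higher. Without 1 library 11 to 15 passed (higher 1 to 6, lower 9 to 11), and 6 of the 13 kept their call in every such fit. Neutrophil, T cell (with NK and dendritic) and neighbouring tissue markers had too few members at a mean CPM of 1, and mitochondrial transcripts none without mitochondrial genes, so these gave no value. The metabolic median was −0.0106 with library totals. The share of genes with an interval within 2-fold was 42.7% with library totals, 27.8% without a filter and 63.2% at a mean CPM of 1 (more or fewer low counts tested), 48.1% with DESeq2, 41.2% with the block, 40.7% without control 2 and PP-MP 1, 48.4% without the length trend, and 35.8% to 43.4% without 1 library. The test of a list turned direction (median in brackets), without control 2 and PP-MP 1, acute phase (−0.0133), extracellular matrix (−0.12) and stellate markers (−0.20); with library totals, female-biased (0.31) and urea cycle genes (0.20); with limma-voom, female-biased genes (−0.23); at a mean CPM of 1 and with fry, urea cycle (0.00249 and −0.0287), metallothionein (−0.0368 and −0.0725) and interferon genes (0.17 and 0.23), with DESeq2, metallothionein genes (−0.0899), without haemoglobin genes, erythrocyte markers (−0.10); and with the block, stellate markers (0.0130). Without control 2 and PP-MP 1 the medians of 8 lists changed sign, among them the called PPAR-alpha (0.03), male-biased (0.02) and acute phase lists. Library totals moved the median of all genes by more than 0.1, from 0.03 to 0.26, so signs of medians under them say nothing of a list, and the tests of PPAR-alpha and male-biased genes kept their lower call (adjusted p = 3.4e-04 and 3.7e-04). Among lists whose test turned without 1 library, medians ranged from −0.41 to 0.14 (PPAR-alpha), −0.18 to 0.10 (cholesterol), 0.10 to 0.25 (endothelial), −0.11 to 0.42 (extracellular matrix), −0.13 to 0.45 (female-biased), −0.135 to 0.0626 (urea cycle), −0.14 to 0.26 (stellate), −0.45 to 0.24 (cholangiocyte), −0.16 to 0.27 (metallothionein) and −0.0263 to 0.51 (interferon). Depth limits genes with few counts, as the share without a filter shows. Simulated changes of 1.5-fold were recovered for 0% of genes, although the changed genes all had a mean CPM of at least 1. That failure is therefore not one of few counts alone.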

Other observations

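Genes of iron and zinc handling moved in both directions, and they are named here after their values were seen. Tfrc, which encodes the transferrin receptor for iron uptake, was at 6.68 ± 0.483 CPM in control and 13.4 ± 2.62 CPM in PP-MP (SD, n = 3 per group), and Mt2, a metallothionein, was at 509, 96.1 and 35.1 CPM in PP-MP 1, 2 and 3 against 13.9 ± 10.7 CPM in control. Hamp2, a relative of the iron hormone hepcidin, was at 28.6 ± 19.2 CPM in control and 3.63 ± 1.18 CPM in PP-MP. Adjusted over the list alone Tfrc and Mt2 rose and Hamp2 fell. With edgeR 0 of the 12 members passed over all genes, 4 had an unadjusted p under 0.05 (3 higher, 1 lower), DESeq2 called 3, and the list missed the camera threshold (adjusted p = 0.99). Egr1, an immediate early transcription factor, rose when adjusted over its list alone, from 4.50 ± 1.34 to 11.5 ± 1.96 CPM, and Bst2, an interferon-induced membrane protein, fell when adjusted over its list alone, from 134 ± 1.96 to 77.9 ± 6.97 CPM. Their lists missed the threshold (camera adjusted p = 0.089 and 0.79), and the median of the interferon list (0.23) and its test (lower) differed in sign. The immediate early list (median 0.45) passed as higher without control 1 (0.51, adjusted p = 0.047) and without PP-MP 3 (0.57, adjusted p = 0.018; 0.018 to 0.37 over the 6 left-out libraries), and its median was 0.10 without PP-MP 1.

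Genes known for higher expression in female liver had a median log2 fold change of 0.08 over 21 genes (camera adjusted p = 0.83), and the direction of that list turned under several alternatives. Cux2, a transcription factor of female liver, was at 0.235 ± 0.0544 CPM in control and at 5.64, 1.31 and 3.41 CPM in PP-MP 1, 2 and 3, and rose when adjusted over the list alone. With edgeR 0 members passed over all genes, 4 had an unadjusted p under 0.05 (3 higher, 1 lower), and DESeq2 called 3. Without PP-MP 1 the list passed as higher (median 0.45, adjusted p = 0.017; 0.017 to 0.95 over the 6 left-out libraries). Among nuclear long non-coding RNAs, named after their values were seen, Neat1 took 0.00293% ± 0.00237 of counts in control and 0.0185% ± 0.00795 in PP-MP, and Malat1 0.0222% ± 0.0124 and 0.0439% ± 0.00486 (SD, n = 3 per group), and neither passed the edgeR threshold (adjusted p = 0.29 and 0.46).

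In the patterns below, fits that leave out 1 library were planned, but their use as tests was chosen only after the result was seen, as was every other test, except those of the macrophage list without PP-MP 1 (its size) and of small RNAs and histone transcripts. Xenobiotic enzyme genes were lower in PP-MP livers (median log2 fold change −0.69, 35 genes). A lower share of hepatocytes alone would lower hepatocyte genes alike. The median was −0.0483 in 61 other hepatocyte genes, of the urea cycle, lipoprotein and periportal lists (95% interval by bootstrap over genes, −0.141 to 0.0287). A lower share alone therefore does not account for the gap between these genes and the xenobiotic list. TMM factors hold the bulk of genes near 0, so this median cannot show that the share was unchanged. These 3 lists were chosen after the result was seen. Medians of the other metabolic lists ranged from −0.37 (lipogenesis) to −0.02 (drug and lipid transporters). The pericentral list was not used for the 61 genes and had a median of −0.14 over 21 genes (14 lower, 7 higher, camera adjusted p = 0.27). Control 2 did not carry the difference, since its list mean was the lowest of the control libraries (−0.27) and the median without it was −0.72 (−1.02 to −0.37). That fit does not address ribosomal RNA in the other control libraries, whose shares also exceeded those of PP-MP. The lower list mean was not confined to PP-MP 1, since PP-MP 2 (−0.40) and PP-MP 3 (−0.51) both lay below the lowest control library (−0.27). With a control SD of 0.23, this speaks only weakly against inflammation in PP-MP 1 as the whole source. Without PP-MP 1 the median was −0.465 (−0.659 to −0.19), an interval over genes, which are not independent replicates. That interval holds the midpoint between 0 and the value with all libraries, so it does not decide how much PP-MP 1 contributed. Leaving out a library removes all its traits, so a part played by inflammation in PP-MP 1 was not tested by itself and stays open. The diet stays open as well, and it cannot be told apart from a batch that coincides with it.

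Macrophage genes were higher in PP-MP livers (median log2 fold change 0.90, 28 genes). A lower share of hepatocytes would raise the markers of all other cell types alike. The macrophage median exceeded that of 42 endothelial and stellate cell markers by 0.818 (permutation over genes, p = 1e-05, the smallest possible here). Genes are not independent replicates (estimated correlation 0.75 in the macrophage list), so that p cannot decide the question. Relative to the control mean, endothelial markers stood at 0.30, 0.51 and −0.09 in PP-MP 1, 2 and 3, and stellate markers at 0.35, −0.43 and 0.05. Erythrocyte (median 0.37) and neighbouring tissue markers (1.06) were higher too without passing. The gap speaks only weakly against a lower share as the whole source, and a part in the rise stays open. Inflammation in PP-MP 1 could account for the rise in part or in whole. The median without that library was 0.411 (0.265 to 0.676, over genes), but it rests on PP-MP 2 (0.90 from the control mean), since PP-MP 3 (0.03) lay below control 2 (0.08), and without control 2 and PP-MP 1 together the call was lost (0.32, adjusted p = 0.16). More macrophages and more transcripts per macrophage were not tested against each other, and the diet stays open.

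Ribosomal RNA took a higher share of counts in the control libraries. Less complete poly(A) selection in control is a candidate explanation, since 78 genes of small nucleolar, Cajal body and histone transcripts, which lack a poly(A) tail, had a median log2 fold change of −0.471 (−0.668 to −0.313), and the test could have come out the other way. The small nucleolar genes were mixed, with 23 lower and 14 higher, against 6 lower and 0 higher for Cajal body and 31 lower and 4 higher for histone genes. Long non-coding genes had a median of 0.55 (1332 genes). A batch of library preparation that coincides with the diet cannot be told apart from it, since 0 control libraries had an 18S ribosomal RNA share within the PP-MP range and the labels name no batch. No biological explanation was tested.

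The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2 genes and the highest other split 1, and 1 split, the real one, gave as many. For lists the real split gave 13 and the highest other 25, with 7 splits as large. The number of lists called therefore does not set the diet apart from other splits. The metabolic median had a size of 0.237 in the real split and 0.333 in the highest other, with 3 splits as large, and genes with an unadjusted p under 0.05 numbered 2535 and 1575, with 1 split as large. The split that parts control 2, PP-MP 1 and PP-MP 2 from the rest gave the highest other value for lists, the metabolic median and unadjusted p.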
